A study of Mus musculus with 6 samples.

How the data were processed

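Gene expression was measured in whole mouse kidneys at E13.5 on Affymetrix MOE430.2 arrays, which read biotin-labelled cRNA with short oligonucleotides grouped into probe sets. There were 6 arrays, 3 of Fz4-/- and 3 of Fz4+/+ kidneys, and each of 3 litters gave 1 sample of each genotype. The group and the litter of every sample were taken from the labels. The labels speak of biological replicates and of litters, and nothing states whether a sample was 1 embryo or a pool of several. P-values therefore measure the spread between these samples.

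The authors summarised and normalised the scans with RMA, per the submitters' processing notes, which give no version. The deposited values are log2 expression values per probe set, which run from 2.22 to 14.79 over 45101 probe sets, and they were used as deposited with no further normalisation. RMA makes the distributions of the arrays nearly equal, so a change in total RNA per cell could not be seen, and it compresses differences near background. The scans were not used here, so no detection call per probe set was made. The excess of 3' over 5' signal, a sign of RNA quality, was taken from the control probe sets of actin and Gapdh. No column of sample values was left unused.

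Probe sets were named through the platform annotation, with symbols checked by Entrez gene number against RefSeq genes of the assembly GRCm38.p6. The annotation gave 1 gene for 34958 probe sets, several genes for 932 and none for 9211, and probe sets of the last 2 kinds were not named. Entrez numbers matched for 34754 probe sets, and 0 symbols changed. The assembly was used only for names and for the order of neighbouring genes. After 64 control probe sets were left out, 27022 probe sets whose mean over all arrays was at or above the 40th percentile, 5.89 log2, were tested. Where a gene was needed once, its brightest probe set stood for it, which gave 12535 genes.

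The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with genotype as the sole term. Differences are Fz4-/- minus Fz4+/+ on the log2 scale. Single values were compared by exact permutation, whose smallest two-sided p for 3 against 3 is 0.1. The 27 gene lists were tested with limma's camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry. They comprised frizzled receptors, the Fz4 ligand and co-receptors, Wnt beta-catenin targets and the Norrin-Fz4 endothelial response. Kidney lists were ureteric tip, ureteric epithelium and stalk, nephron progenitors, early nephron epithelium, podocytes, renal stroma and endothelium. Lists for other cells were erythroid cells, macrophages, neurons and neural crest, adrenal cortex and gonad, smooth and skeletal muscle, and liver. The remaining lists were proliferation, p53 and apoptosis, hypoxia and glycolysis, immediate early and stress, sex-linked genes, sterol synthesis, hedgehog targets, Ret and FGF response, retinoic acid response, and extracellular matrix and basement membrane.

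The 100 measured genes on either side of Fzd4 were compared with all other measured genes by Fisher's exact test at an unadjusted p of 0.01. Their median absolute difference was also set against 10000 random gene sets. Named genes were fixed by rule. Fzd4 came first. Genes past the threshold with values that did not overlap between the genotypes came next. Since these were under 20, the genes with the smallest unadjusted p followed, up to 10 in each direction, among those with an absolute difference of at least 0.5 and no overlap. Up to 4 members of each list with the smallest unadjusted p were named as well. The tests, lists, rule and first set of alternatives were fixed before the data were examined.

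The labels tie equal replicate numbers to a shared litter, so the numbers pair the samples. Deviations from the genotype means correlated across probe sets by 0.577, 0.178 and 0.809 in litters 1, 2 and 3. The Fz4-/- sample of litter 1 correlated best with the Fz4+/+ sample of litter 2, at 0.609. The fit with the litter as a block was among the alternatives fixed then.

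The fits were tested on simulated data with the residual spread of the 27022 probe sets and 50 changed ones of each size. Without the block, the share recovered was 0% of changes of 0.5 log2, 40% at 1, 80% at 2 and 98% at 4. With the litter block it was 0%, 26%, 68% and 88%. The simulated noise was drawn independently for each probe set and sample. Without the block it gave 5.35% of unchanged probe sets an unadjusted p under 0.05. The measured data gave 239 of 27022, and Fzd4, at -6.16, was not called. The shares recovered therefore do not carry over to the measured data. Other alternatives fixed then covered the filter, the normalisation, the variance prior, array weights, probe set choice, a sex score as a covariate, and each sample left out in turn. The sex score as first written included Ddx3y, for which the annotation gave no probe set of its own, so it was the mean of Eif2s3y, Kdm5d and Uty minus Xist. Alternatives added after the data were seen used the first principal component as a covariate or left out litter 3. They also combined these or the litter block with trend or robust priors. Others matched the random sets of the neighbour test and left Fzd4 out of the Norrin-Fz4 endothelial response.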

Results

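The expression of genes in whole kidneys was measured in 3 Fz4-/- and 3 Fz4+/+ samples at E13.5, when the ureteric bud branches into mesenchyme that holds the nephron progenitors. Fz4 is the protein of Fzd4, a receptor for Wnt ligands and for Norrin. Each litter gave 1 sample of each genotype. The median log2 signal of the arrays lay between 6.62 and 6.74, and the number of arrays limits the precision. The first principal component took 70.8% of the variance and set both samples of litter 3 (48.7 in Fz4-/- and 70.1 in Fz4+/+) apart from both of litter 1 (-36.3 and -33.5). Its difference between the genotypes had an exact permutation p of 0.9.

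Fzd4 was lower in every Fz4-/- sample than in every Fz4+/+ sample. On the first of its probe sets the Fz4-/- samples of litters 1 to 3 read 4.37, 3.58 and 6.22 and the Fz4+/+ samples 11.21, 11.12 and 10.31, a difference of -6.16 ± 0.68 (SE). On the second they read 4.33, 4.05 and 5.05 against 7.53, 7.72 and 8.48, a difference of -3.44 ± 0.35 (SE). No fold is given, because most Fz4-/- readings lay near background, where RMA compresses differences. The third probe set was near background in both genotypes, at 3.07 ± 0.12 and 3.07 ± 0.04 (SD, n = 3). The exact permutation p was 0.1 for each of the first 2 probe sets, the smallest that 3 against 3 can give, and 1 for the third. Adjusted over the 3 Fzd4 probe sets alone, limma's p was 0.000138 for the first 2, whereas over all probe sets it was 0.999988 for both. With the litter as a block, limma's adjusted p over all probe sets was 0.999986 for the first and 0.129 for the second. Where the probe sets lie relative to the altered part of the gene was not analysed here.

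**Figure D1:**
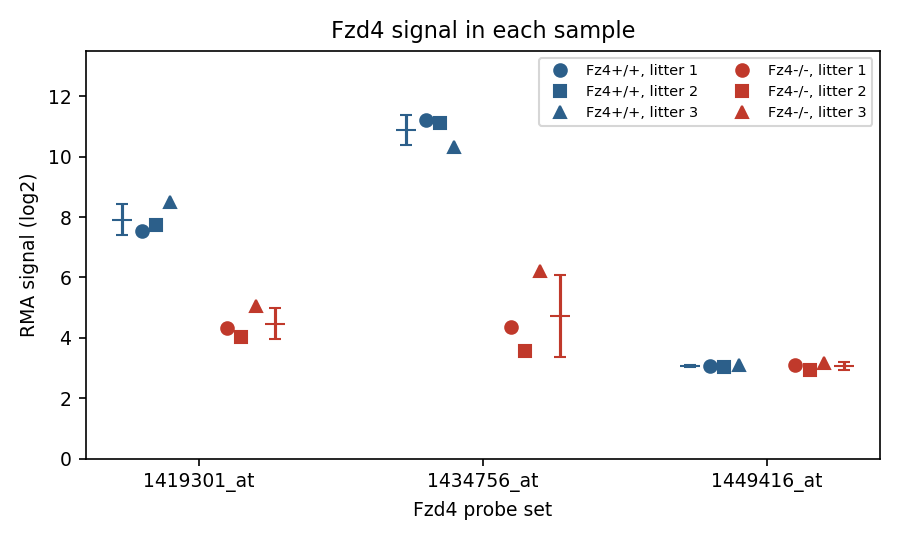
RMA signal (log2, vertical axis) of the 3 Fzd4 probe sets (horizontal axis) in each sample, with colours for genotype, symbols for litter, and bars for the mean and SD of 3 samples. On the probe set drawn in the middle the Fz4-/- samples read 3.58 to 6.22 and the Fz4+/+ samples 10.31 to 11.21.

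Which other genes differ between kidneys with and without Fzd4 was asked across all tested probe sets. No gene passed the threshold, and Fzd4 had the smallest unadjusted p among the named genes. limma called 0 of 27022 probe sets, with 239 at an unadjusted p under 0.05 (154 higher and 85 lower in Fz4-/-) where 1351.1 would be met by chance. Without moderation the count was also 0, with 415 at an unadjusted p under 0.05. Array weights called 2 probe sets at an adjusted p of 0.0370, and both were Fzd4. Values of the genotypes did not overlap for 983 probe sets, or 3.64%, where chance gives 10% of exchangeable samples. Litters pair these samples, and 21.5% of probe sets had the same direction in all 3 litters, where chance gives 25%. The unadjusted count of 239 became 404 without the Fz4-/- sample of litter 1, 124 without that of litter 2 and 1725 without the Fz4+/+ sample of litter 3. It was 841 with the litter as a block, with 0 calls, and 940 with the litter as a random effect. Array weights gave 6084 (4386 higher and 1698 lower), above the number expected by chance. They weighted the Fz4-/- sample of litter 2 by 8.81, against 0.66 and 0.51 in litters 1 and 3. The Fz4+/+ sample of litter 1 had 2.99, against 0.52 and 0.22 in litters 2 and 3. The weighted fit, its 2 calls included, thus rested largely on 1 sample of each genotype, from different litters. Chosen after the data were seen, the first principal component as a covariate gave 1209 and leaving out litter 3 gave 1102.

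After Fzd4, genes were named by unadjusted p among those that differed by at least 0.5 without overlap, and none passed the threshold. By p alone Ntn1 (0.43, limma's unadjusted p of 0.0101) and Cited1 (-0.33, unadjusted p of 0.0149) came before most of them. Among the 10 higher ones, Prkaa2, a catalytic subunit of AMP-activated kinase, differed by 0.56 ± 0.13 (SE). Fabp4, a fatty acid binding protein, differed by 0.61 ± 0.18, the tight junction gene Cldn1 by 0.77 ± 0.23 and the folate receptor gene Folr1 by 0.76 ± 0.22. Nfix, Tmem191c, Ptgfr, Nr5a2, Scin and Ndnf lay between 0.51 and 0.85. Among the lower ones, Pnmt, which encodes the enzyme that makes adrenaline, differed by -0.71 ± 0.22 (SE). The muscle genes Actn2, Apobec2, Synpo2l and Actc1 differed by -0.55, -0.74, -0.92 and -0.85. Tnfrsf13c, Ubxn10, Prr29 and Zim3 lay between -0.78 and -0.53. limma's adjusted p was 0.999988 for each of them, and their unadjusted p ran from 0.00504 for Prkaa2 to 0.0833 for Actc1. Without the Fz4-/- sample of litter 2 the difference was -0.50 for Actc1 and -0.58 for Synpo2l. Without the Fz4+/+ sample of litter 2 it was -0.50 for Actc1, -0.36 for Actn2, -0.37 for Prr29 and -0.35 for Ubxn10. It was -0.40 for Zim3 without the Fz4-/- sample of litter 3 and -0.50 for Tnfrsf13c without the Fz4+/+ sample of litter 3. The rule found 25 such genes, 15 higher and 10 lower, Fzd4 included. The second probe set of Nr5a2 went the other way, as did 1 of the 3 other probe sets of Nfix.

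In the gene lists, camera called the ureteric epithelium and stalk higher in Fz4-/- kidneys, and the nephron progenitors and the ureteric tip lower, with no single member past the threshold. None of these 3 calls held with an estimated correlation, each at an adjusted p of 0.427. Over all tested probe sets the median difference was 0.0334, or 0.00978 after quantile normalization. Counts above or below 0 are not corrected for this offset, whereas camera compares each list with the other genes. Of 28 measured ureteric epithelium genes 27 were above 0, with a median of 0.21 and a camera adjusted p of 2.55e-08. Perp, Scnn1b, Cdh1 and Krt7 read 0.73, 0.39, 0.24 and 0.50. The mean of the list was higher in Fz4-/- in all 3 litters, by 0.05, 0.54 and 0.18, with an exact permutation p of 0.1, the smallest possible. Without the Fz4+/+ sample of litter 2 the median was 0.0948 and camera's adjusted p 0.000177. Without that of litter 3 these were 0.252 and 0.0103. The Fz4+/+ sample of litter 2 had the lowest means of the ureteric epithelium, early nephron, podocyte and endothelial lists and the highest of the muscle list. It lay apart on the second principal component, at -32.7 against -10.5 to 20.1. Its excess of 3' over 5' signal, which grows as RNA degrades, was 0.90 log2 for actin and 0.90 for Gapdh, against 0.75 and 0.76 in the Fz4-/- sample of its litter. It did not stand apart in this from all others. The Fz4+/+ sample of litter 3 read 0.76 and 0.90, and the Fz4-/- sample of litter 1 read 0.86 and 0.86. Between the genotypes this excess differed by -0.06 for actin and -0.07 for Gapdh, with exact permutation p of 0.4 and 0.2.

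Of 27 nephron progenitor genes 19 were below 0, with a median of -0.09 and a camera adjusted p of 2.52e-06, or an adjusted p of 0.427 with an estimated correlation. Cited1, a marker of uncommitted progenitors, read -0.33, Eya1 -0.26 and Gdnf, the ligand of Ret, -0.25. The list was lower in all 3 litters, with an exact permutation p of 0.3, and its median was -0.163 without the Fz4+/+ sample of litter 1 and -0.0557 without the Fz4-/- sample of litter 3. Of 25 ureteric tip genes 15 were below 0, with a median of -0.05 and a camera adjusted p of 0.00195. Of 21 genes of the Ret and FGF response 16 were below 0, with a median of -0.07 and an adjusted p of 0.000226. The adjusted p was 0.427 for each of these 2 lists with an estimated correlation. The exact permutation p of the list mean was 0.1 for the tip and 0.5 for Ret and FGF. Etv4, Sox8 and Ret read -0.33, -0.48 and -0.18, whereas Clu, of the tip list, read 0.26. Other lists held 14 of the 25 tip genes and 15 of the 21 Ret and FGF genes. Camera's adjusted p for the tip list was 0.449, with a median of -0.0233, without the Fz4-/- sample of litter 3, 0.0689 without the Fz4+/+ sample of litter 1 and 0.168, with a median of -0.0217, without that of litter 2. The tip median was -0.0813 without the Fz4-/- sample of litter 1 and -0.0871 without the Fz4+/+ sample of litter 3. For Ret and FGF camera's adjusted p was 0.804, with a median of 0.00317, without the Fz4-/- sample of litter 3. Without the filter on low signal both calls were lost, at camera's adjusted p of 0.0700 and 0.0525. With the mean of a gene's probe sets the median was -0.0319 for each.

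Camera called the lists of muscle, nerve, liver and macrophages lower in Fz4-/- samples, though not in every litter. None of these 4 calls held with an estimated correlation, at an adjusted p of 0.427 for muscle and nerve and 0.804 for liver and macrophages. Of 22 muscle genes 18 were below 0, with a median of -0.36 and a camera adjusted p of 1.21e-10. Acta2, Actc1, Myh3 and Tnnt2 read -0.35, -0.85, -1.16 and -0.84. The muscle mean differed by -1.47 in litter 2, -0.04 in litter 1 and 0.12 in litter 3. Its exact permutation p was 0.4. Its median was -0.620 without the Fz4-/- sample of litter 1, -0.216 without that of litter 2 and -0.548 without the Fz4+/+ sample of litter 3. Of 21 neural genes 13 were below 0, with a median of -0.17 and a camera adjusted p of 0.00255, or an adjusted p of 0.427 with an estimated correlation. The chromaffin granule genes Chgb and Chga read -1.86 and -0.80, and Isl1 read -1.19. The neural mean differed by 0.02, -0.48 and -0.21 in litters 1 to 3, with an exact permutation p of 0.3. Without the Fz4+/+ sample of litter 2 the neural median was -0.0573 and camera's adjusted p 0.168. The median was -0.0987 without the Fz4-/- sample of litter 1, -0.0617 without the Fz4+/+ sample of litter 3 and -0.104 with the mean of a gene's probe sets.

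Of 12 liver genes 9 were below 0, with a median of -0.40 and a camera adjusted p of 0.00195, or an adjusted p of 0.804 with an estimated correlation. Ttr, Fgb and Ambp read -1.27, -0.49 and -0.48, whereas Hnf4a, which early nephrons also express, read 0.89. Litter 3 gave -1.05 and the others 0.02 and 0.11, with an exact permutation p of 0.8. Of 26 macrophage genes 17 were below 0, with a median of -0.05, a camera adjusted p of 0.000144 and an adjusted p of 0.804 with an estimated correlation. Lyz1, Cd53 and F13a1 read -0.21, -0.33 and -0.57. The macrophage mean differed by -0.0054, 0.01 and -0.30 in litters 1 to 3, with an exact permutation p of 0.8. Without the Fz4+/+ sample of litter 3 the macrophage median was 0.102 and camera's adjusted p 0.465, and without the Fz4-/- sample of litter 2 these were -0.0260 and 0.0590. The median was -0.154 without the Fz4-/- sample of litter 3, and -0.116 and -0.222 without the Fz4+/+ samples of litters 1 and 2. The liver call was lost without the Fz4-/- samples of litters 2 and 3, at camera's adjusted p of 0.188 and 0.140 and medians of -0.0891 and -0.308. It was also lost without the Fz4+/+ samples of litters 1 and 3, at 0.443 and 0.171 and medians of -0.206 and -0.0749. The liver median was -0.623 without the Fz4-/- sample of litter 1 and -0.654 without the Fz4+/+ sample of litter 2.

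**Figure D2:**
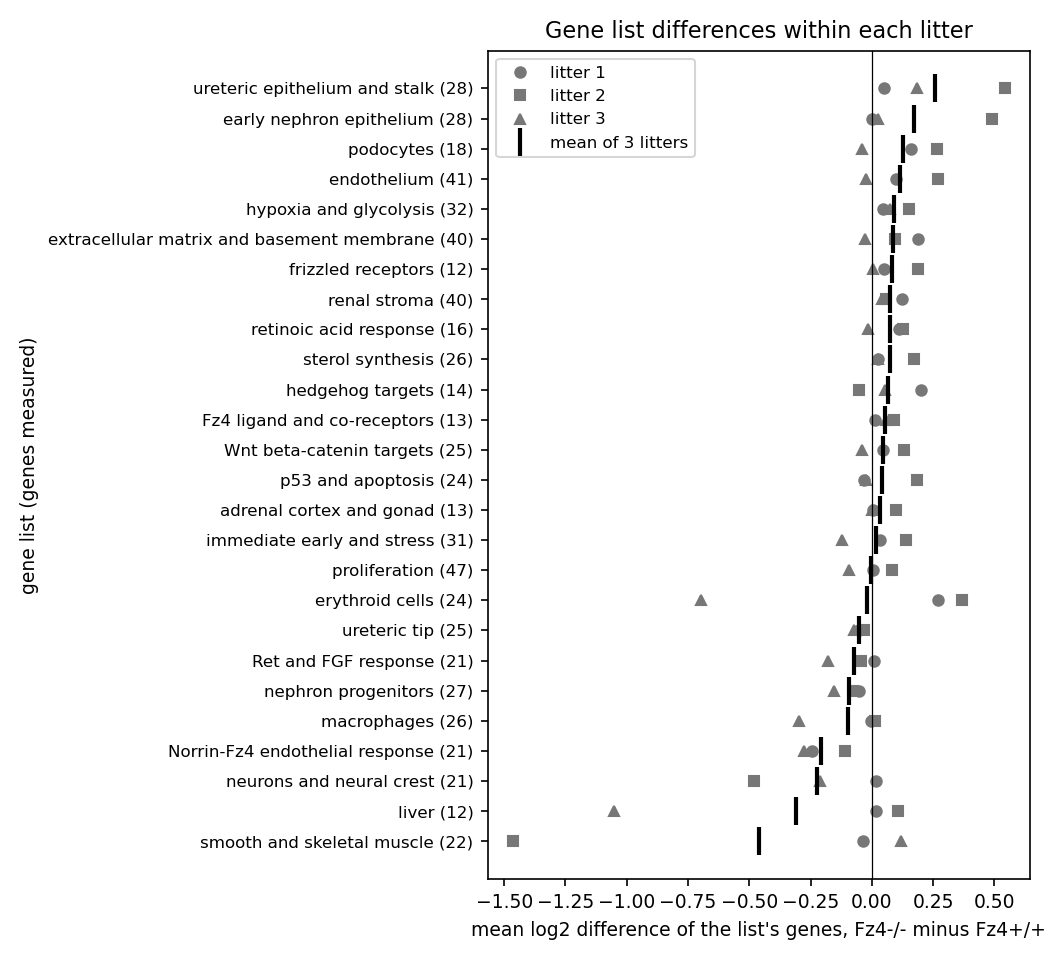
Mean log2 difference of each gene list, Fz4-/- minus Fz4+/+ (horizontal axis), for the lists other than sex-linked genes (vertical axis, genes measured in brackets). Symbols are the 3 litters and bars their mean; the ureteric epithelium list lies above 0 in all 3 litters, at 0.05, 0.54 and 0.18, while the muscle list is at -1.47 in litter 2 and at -0.04 and 0.12 in the others.

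Camera called the lists of endothelium, early nephron epithelium, podocytes and the extracellular matrix higher in Fz4-/- kidneys, by small amounts. None of these 4 calls held with an estimated correlation, at an adjusted p of 0.844 for the matrix and 0.804 for the others. In litters 1 to 3 the endothelial mean differed by 0.10, 0.27 and -0.03, podocytes by 0.16, 0.27 and -0.04 and the matrix by 0.19, 0.09 and -0.03. The early nephron mean was higher in each, by 0.0021, 0.49 and 0.02. The exact permutation p was 0.5 for endothelium, 0.2 for early nephron, and 0.4 for podocytes and for the matrix. Of 41 endothelial genes 35 were above 0, with a median of 0.10 and a camera adjusted p of 0.00994. Cldn5, Sox18 and Kdr read 0.25, 0.26 and 0.18. Of 28 early nephron genes 24 were above 0, with a median of 0.11 and a camera adjusted p of 0.00600. Bmper read 0.27 and Lrp2, the endocytic receptor megalin, 0.84. Of 18 podocyte genes 14 were above 0, with a median of 0.08 and a camera adjusted p of 0.0358. Synpo and Ptpro read 0.27 and 0.66. Of 40 matrix genes 37 were above 0, with a median of 0.07 and a camera adjusted p of 0.0281. Lama1 and Lama5 read 0.29 and 0.30. With the litter as a block camera's adjusted p became 0.111 for podocytes and 0.0610 for the matrix, so these 2 calls were lost. Without the Fz4-/- sample of litter 2 and the Fz4+/+ sample of litter 1 in turn, camera's adjusted p for endothelium was 0.0536 and 0.0815. The endothelial median was 0.0556 without the Fz4-/- sample of litter 3 and 0.195 without the Fz4+/+ sample of litter 3. For early nephron camera's adjusted p was 0.474 and 0.0590 without the Fz4-/- samples of litters 1 and 2, 0.533, with a median of -0.00129, without the Fz4+/+ sample of litter 2, and 0.579, with a median of 0.186, without that of litter 3. The early nephron median was 0.178 without the Fz4-/- sample of litter 3 and 0.200 without the Fz4+/+ sample of litter 1. The matrix call was lost without the Fz4-/- samples of litters 1 and 2, at 0.352 and 0.0536, and without the Fz4+/+ samples of litters 1 and 3, at 0.982 and 0.0591 and medians of -0.00274 and 0.160. The podocyte call was lost without any sample but the Fz4-/- one of litter 3, where the median was 0.121, and the median was 0.148 without the Fz4+/+ sample of litter 3.

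Lists of Wnt and Norrin signalling did not pass camera. Medians of 0.05 to 0.07 lie near the median difference of 0.0334 over all tested probe sets. Of 25 Wnt beta-catenin targets 18 were above 0, with a median of 0.05 and a camera adjusted p of 0.675, and Rnf43 and Apcdd1 read 0.44 and 0.14. Of 12 frizzled receptor genes 8 were above 0, with a median of 0.05 and an adjusted p of 0.675. Fzd6 read 0.22 ± 0.14 (SE) and Fzd8 0.48 ± 0.88, with limma's unadjusted p of 0.163 and 0.606. Fzd8 rose from litter 1 to litter 3 in both genotypes. With the litter as a block its SE was 0.18 and limma's unadjusted p 0.0486. Of 13 ligand and co-receptor genes 7 were above 0, with a median of 0.07 and an adjusted p of 0.577. Dvl2, Wnt9b and Dvl3 read 0.28, 0.30 and -0.17. With the mean of a gene's probe sets this last list had a median of 0.142 and camera's adjusted p was 0.0329. Of 21 genes of the Norrin-Fz4 endothelial response 17 were above 0, with a median of 0.11 and a camera adjusted p of 0.675. The mean of that list was -0.21 because it includes Fzd4, so its mean differs in sign from its median and its test. Without Fzd4, a setting chosen after the data were seen, the list had a median of 0.113 and a camera adjusted p of 0.148.

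The other lists did not pass camera either, though some did when a sample or setting was changed. Of 40 stromal genes 27 were above 0, with a median of 0.04 and an adjusted p of 0.353, and Ntn1 and Mfap5 read 0.43 and 0.60. Hedgehog targets (9 of 14 above 0, median 0.07, adjusted p 0.4) included Gli1 at 0.34. Retinoic acid genes (11 of 16 above 0, median 0.08, adjusted p 0.624) included Tgm2 at 0.37 and Aldh1a3 at 0.28. Proliferation genes (23 of 47 above 0, median -0.0011, adjusted p 0.167) included Tk1 at 0.13 and Mcm3 at -0.10. Hypoxia and glycolysis genes (25 of 32 above 0, median 0.08, adjusted p 0.116) included P4ha1 at 0.33, and sterol synthesis genes (21 of 26, median 0.08, adjusted p 0.109) included Mvd at 0.22. Genes of p53 and apoptosis (12 of 24 above 0, adjusted p 0.675) had a median of -0.00080 and a mean of 0.04, with camera's direction lower. Immediate early genes (19 of 31 above 0, adjusted p 0.624) had a median of 0.05 and a mean of 0.02, also with camera's direction lower. Erythroid genes (13 of 24 above 0, adjusted p 0.296) had a median of 0.0048, a mean of -0.02 and camera's direction lower. Adrenal and gonadal genes (9 of 13 above 0, median 0.06, adjusted p 0.863) included Scarb1 at 0.21. Without the Fz4+/+ sample of litter 2, camera's adjusted p was 0.00305 for stroma (median 0.0720), 0.000863 for erythroid genes (median -0.157), 0.0202 for hedgehog targets (median 0.142) and 0.0489 for proliferation (median -0.0474). Without the Fz4-/- sample of litter 1 it was 0.0161 for erythroid genes (median -0.0353) and 0.0197 for hypoxia and glycolysis (median 0.144). Hypoxia and glycolysis also passed without the filter, at 0.0161, and with the mean of a gene's probe sets, at 0.00875, and sterol synthesis passed without the filter, at 0.0191. Without litter 3 erythroid genes passed as higher, at 0.00627 with a median of 0.279. The medians of retinoic acid genes, stroma and hedgehog targets were -0.0294, -0.0235 and -0.0109 without the Fz4+/+ sample of litter 1. They were 0.215, 0.127 and 0.178 without that of litter 3.

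Of the 27 lists 12 passed camera, 5 higher and 7 lower in Fz4-/-. With the sex score as a covariate 9 passed, since the liver, matrix and podocyte calls were lost at camera's adjusted p of 0.116, 0.449 and 0.107. The median was then -0.256 for liver, 0.0194 for the matrix and 0.0679 for endothelium, and that of macrophages was -0.0866. After quantile normalization or median centring the podocyte call was lost, at 0.0548 and 0.0572, as it was at 0.184 with the first principal component as a covariate. Quantile normalization gave a median of 0.0620 for endothelium and -0.0890 for macrophages. Without litter 3, chosen after the data were seen, the macrophage, liver and Ret and FGF calls were lost, at 0.197, 0.460 and 0.0836. With an estimated correlation 0 passed, and with fry 0 passed, for a shift 1 way and for change in either direction. In every list 0 members passed over all genes tested. Adjusted over the list alone 1 member, Fzd4, passed in the Norrin-Fz4 endothelial response, and 0 passed in every other list.

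Genes beside Fzd4 can keep sequence of the stem cell strain in which it was targeted, so its neighbours were examined. Of the 200 nearest measured genes 0 had an unadjusted p under 0.01, against 3 of 12307 others (Fisher's exact test, two-sided p = 1). Folr1 and Saxo2 read 0.76 and -0.48, with limma's unadjusted p of 0.0140 and 0.0342. The median absolute difference of the neighbours was 0.0940 against a median of 0.0757 in random sets (permutation p = 0.0107). With random sets matched on mean expression, chosen after the data were seen, the random median was 0.0818 and the permutation p 0.0568. The nearest 50 on either side gave 0.140 and a permutation p of 1e-04, the smallest that the draws can give, also with random sets matched on residual SD. For the 200 genes the permutation p was 0.0603 without the Fz4-/- sample of litter 3 and 0.158 without the Fz4+/+ sample of litter 1. Without the Fz4+/+ sample of litter 3 the neighbours gave 0.179, where random sets gave 0.140.

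Transcripts of the Y chromosome were read in 5 of the 6 samples, and Xist, which is transcribed from an inactive X, in every sample. Eif2s3y read 4.48 in the Fz4+/+ sample of litter 1 and 9.74 to 10.89 in the others. Xist read 12.05 to 12.54. In the Fz4+/+ sample of litter 1 Kdm5d and Uty also read lowest, at 3.71 and 3.75. The others read 7.07 to 8.23 and 5.56 to 7.78. That sample thus showed no clear RNA of male embryos. A single embryo is not known to give both signals at such levels. The 5 samples with both may therefore be pools of embryos of both sexes, though nothing states whether a sample was 1 embryo or a pool. The sex score differed by 1.04 between the genotypes, with an exact permutation p of 0.9, and by -0.62 without the Fz4+/+ sample of litter 1. Of the 8 measured sex-linked genes 5 were above 0, with a median of 0.03, a mean of 0.36 and a camera adjusted p of 0.985.

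**Figure D3:**
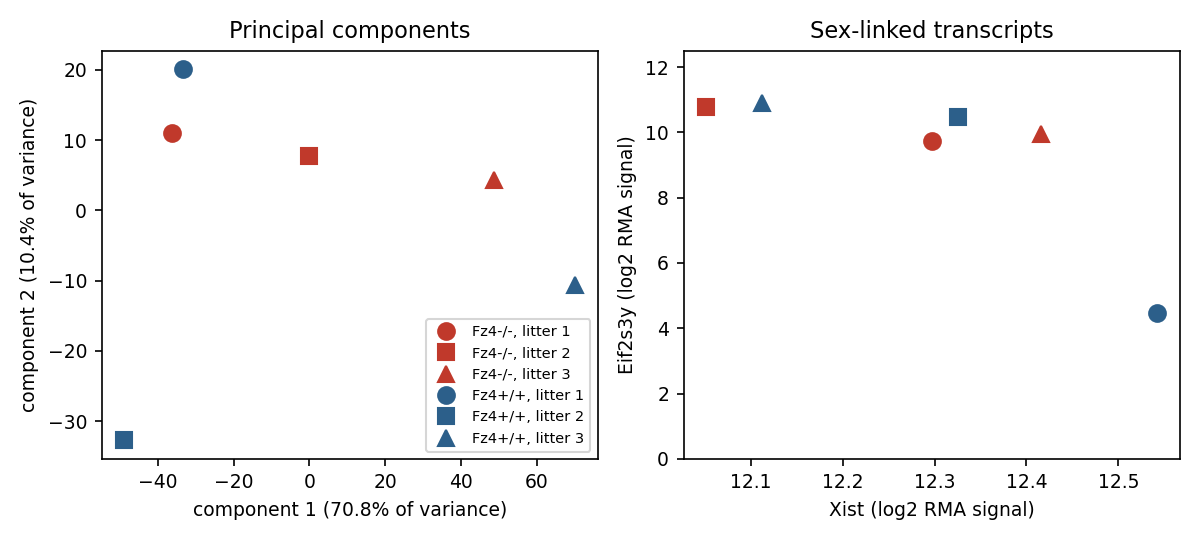
The first 2 principal components of the tested probe sets (left, unitless scores) and Eif2s3y against Xist (right, log2 RMA signal) in the 6 samples, with colours for genotype and symbols for litter. Both samples of litter 3 have the highest scores on component 1 (48.7 and 70.1), and Eif2s3y is at 4.48 in the Fz4+/+ sample of litter 1 and between 9.74 and 10.89 in the others.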

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

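The settings with the first principal component, without litter 3, with combined priors and with matched random sets, and each sample left out for the neighbours and the sex score, were chosen after the data were seen. The count of 0 probe sets became 2 with array weights and 1 both with the litter as a block with trend and robust and with the first principal component with trend and robust, and these probe sets were Fzd4. Every other fit, the litter block with 0 included, gave 0. The fit with array weights rested largely on 1 sample of each genotype. The 239 at an unadjusted p under 0.05 became 6084 with array weights, 940 with the litter as a random effect, 841 with it as a block, 531 without the filter, 415 without moderation, 126 with trend and robust, and 141 and 121 with fewer probe sets tested (a filter at the 60th percentile, 1 probe set per gene). It was 1209 with the first principal component, 1102 without litter 3 and 757 to 1165 in fits that combined these or the block with another choice. The Fzd4 difference stayed between -6.90 and -5.58 when single samples were left out. The count of 12 lists became 0 with an estimated correlation and 0 with fry, and ran from 6 to 12 when single samples were left out; it was 10 with the litter as a block, which ended the podocyte and matrix calls and changed no other call, and 9 with the sex score, which ended the liver, matrix and podocyte calls. It was 12 without the filter, where the tip and Ret and FGF calls were lost and 2 others gained, and 14 with the mean of a gene's probe sets, which lost none and gained 2. The erythroid list turned to 0.279 without litter 3. The matrix median ran from -0.00274 to 0.160 when single samples were left out. The cause was not tested. The neighbour median of 0.0940 had a p of 0.0568 and 0.103 when only the random sets were changed, to ones matched on mean expression or on residual SD, and ran from 0.0863 to 0.179 when single samples were left out, with p from 0.0023 to 0.158. The sex score difference ran from -0.622 to 2.09 when single samples were left out. All 19 named genes other than Fzd4 kept their direction in each setting tried, though 7 of them moved by over 1.5 times when a sample was left out. They were chosen for values without overlap, so leaving out a sample could not turn a direction. The litter block leaves the difference itself unchanged. Their kept directions are therefore no separate support. Signal near background limits the Fzd4 differences.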

Other observations

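Except for the sex score and the counts of splits, the tests in this part were chosen after the result they bear on was seen. Some groups of genes differed between litter 3 and litter 1 (2 samples each), with list means that went the same way in both genotypes, for some by little. The median of hypoxia and glycolysis genes was higher by 0.32, with 1 of 32 genes below 0, outside the central 95% of matched random sets, 0.03 to 0.22. Stromal genes were higher by 0.21, also outside their range, which ended at 0.18. Below their ranges lay the medians of the ureteric tip at -0.06, Ret and FGF at -0.08, muscle at -0.08 and early nephron at -0.13, lists that also passed camera between the genotypes. Erythroid genes (0.36), liver genes (-0.21) and Wnt targets (-0.05) lay outside their ranges too, but their list means went opposite ways in the 2 genotypes. From litter 1 to litter 3 the centred erythroid mean went from -0.17 to 0.64 in Fz4+/+ and from 0.11 to -0.05 in Fz4-/-, and the liver mean from 0.41 to 0.73 and from 0.42 to -0.32.

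The first principal component set litter 3 apart, at 48.7 and 70.1, while litters 1 and 2 overlapped, with the Fz4-/- sample of litter 2 at -0.1 and the others at -48.9 to -33.5. The 73 probe sets of olfactory and vomeronasal receptors below the filter were lower in litter 3 than in litter 1. Their median was -0.31, with 65 below 0, outside the matched range of -0.15 to 0.01. These probe sets are dim, so background of labelling or hybridization is a candidate explanation. Receptor RNA in kidney was not excluded, and why receptors moved more than other dim probe sets was not tested. For a difference in stage the early nephron median of -0.128 lay outside its matched range, and the podocyte median of 0.09 inside, so stage cannot be told apart from other differences between litters. No biological explanation from the genotypes was tested for it.

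Fzd4 read 6.22 on the first probe set in the Fz4-/- sample of litter 3, above 4.37 and 3.58 in the others. Of 5746 probe sets at the same level 1 rose as much in that sample, or 0.0174%, which argues against the first principal component for this probe set. Fzd4 RNA in that sample would raise the second probe set too, but there 3.20% of probe sets rose as much, and near background this decides nothing. Fzd4 RNA in that sample, whose source was not tested, therefore cannot be told apart from other causes.

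The ureteric epithelium list was higher in Fz4-/- in all 3 litters, most in litter 2, and its call was lost with an estimated correlation. Its median was 0.198 with the first principal component as a covariate and 0.228 with the sex score, against 0.214 without, which argues against either as the whole cause. Fewer cells of other tissues in the Fz4-/- samples would raise every kidney list. The ureteric tip mean instead differed by -0.0536, lower in all 3 litters without overlap of the genotypes. This cannot decide the question, because the difference was small and chance gives no overlap in 10% of exchangeable samples. Several lists were examined, and the call of the tip list is itself lost without single samples and with an estimated correlation. The gap between progenitor and ureteric means (-0.35, exact permutation p of 0.1, the smallest possible) cannot decide it either. That gap contains the ureteric rise itself, and the progenitor mean alone had an exact permutation p of 0.3. In litter 3 the muscle mean was higher by 0.12, but the liver, neural and macrophage means differed by -1.05, -0.21 and -0.30. Means of 4 other kidney lists were above 0. A difference between the genotypes, fewer cells of other tissues and the amount of ureter kept at dissection may account for the list. Since the median was 0.0948 without it, the Fz4+/+ sample of litter 2 may account for part of the size, through its RNA or otherwise. All stay open.

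The 6 samples can be split in 10 ways, too few for a share under 0.05. The real split gave 0 probe sets past the threshold. All 10 splits give at least 0, so this count cannot set the real one apart. The highest other gave 667. At an unadjusted p under 0.05 it gave 239, met by 9 of the 10 splits, with 8480 as the highest other. For gene lists it gave 12, met by 1 split, itself, with 10 as the highest other. The split with 667 set the Fz4-/- sample of litter 1 and the Fz4+/+ samples of litters 1 and 2 against the rest. Those samples were the lowest on the first principal component, at -36.3, -33.5 and -48.9, against -0.1, 48.7 and 70.1. That split thus follows this component. Among the splits that part all 3 litter pairs, the others gave 233, 269 and 506 probe sets at an unadjusted p under 0.05 and 7, 8 and 10 lists.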
